A study of Homo sapiens with 8 samples.

How the data were processed

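The series holds 8 arrays of tumour RNA (total RNA, biotin-labelled), 4 from SK-OV-3 cells with a BORA vector and 4 from cells with an empty vector (EV), grown in nude mice. Groups and replicate numbers were taken from the sample labels. The deposited table holds 1 value per probe set and array. The authors' processing used Affymetrix Expression Console, per the submitters' processing notes; its version, the background correction, the summary and the normalization are not given in the sources used here. The deposited values were taken as log2 signals from their range, since no label states the log base; folds are powers of 2 of their differences and hold only on that reading. The array is also uncertain: the series' description names the Human Gene 1.0 ST array, while the row identifiers and the annotation supplied with the series belong to another Affymetrix human design.

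The table has 24351 rows. The supplied annotation lists 1 gene symbol each for 17709 transcript clusters and several for 0, and 20 symbols have more than 1 cluster. A further 3739 clusters are not listed there, which leaves them unnamed here, and 2903 rows are controls (612 negative, 2197 positive and 8 spiked-in bacterial and phage controls among them). All 17709 identifiers matched a gene table of the GRCh38.p14 assembly, used only for current symbols and for the order of neighbouring genes; no coordinates are printed, since the sources name no genome build. The 8 arrays were separate: at most 0.0113% of values were identical between 2 arrays. Human probes can bind mouse RNA only where sequences allow, so host transcripts may be read in part.

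No further normalization and no filter on dim clusters was applied in the main setting. Each of the 17709 clusters was tested with limma (lmFit and eBayes, no covariates), BORA minus EV, with Benjamini-Hochberg adjustment and a threshold of 0.05. Labels name no scan date or slide, so no batch was tested. The sample titles carry serial numbers in which all BORA tumours precede all EV tumours. Any order of processing behind these numbers cannot be told apart from the groups. The 29 gene lists, with 507 entries and 492 distinct genes, were fixed before the data were examined; 429 of these genes were measured, 1 through a synonym. The 28 lists with at least 5 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, on the brightest cluster of each gene, with adjustment over the lists; the list of mitochondrially encoded transcripts had 0 measured members and was not tested. A list's mean, median and counts are over its measured members, and the SE of a mean comes from the list's scores per tumour. The counts called adjusted over the list alone adjust limma's p-values within that list. The BORA transcript was also tested with a two-sided exact permutation test.

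Named genes followed a rule set before the data were examined: BORA; the 12 largest rises and 12 largest falls past the threshold with no overlap between groups; where none passed in a direction, the 5 with the smallest p, given as values that did not pass; and up to 4 members with the smallest p of each list described. 1 gene that the rule names is not reported here. The same rule was applied to the 7 arrays without EV replicate 1. That second set of results, and its alternatives, were chosen after the data were seen, as was the comparison of each named gene and list member with the 95th percentile of the negative controls, averaged over the arrays of its group. The shares of dim genes and of markers that were lower, with and without quantile normalization, were also counted after the data were seen.

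The alternatives were the replicate number as a block, quantile normalization, centring on each array's median, an intensity trend with robust fitting, array quality weights, 2 filters on dim clusters, all rows of the table, the ordinary test without moderation, 2 other thresholds, an estimated inter-gene correlation, the fry test, the mean of all clusters of a gene, and leaving out each array. The steps were tested on simulated data with the real cluster means and with spreads drawn from limma's fitted prior. Over 8 arrays, 41.8% of 67 clusters changed by 1 log2 unit were recovered, 88.1% of those changed by 2 and 98.5% of those changed by 4, with 5 false calls among 157. Without EV replicate 1 the shares were 55.2%, 98.5% and 100%, with 7 false calls among 176, and the list test found the 1 shifted list and 0 others in both. Clusters were simulated as independent of each other, and no array was made to stand apart. The simulation therefore cannot show how the list test behaves where genes are correlated. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used.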

Results

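RNA was measured on Affymetrix expression arrays in 8 tumours grown in nude mice from SK-OV-3 cells, a human ovarian cancer line. In 4 tumours the cells carried a vector that overexpresses BORA, a cofactor through which Aurora A activates PLK1 at mitotic entry. In the other 4 the cells carried the empty vector (EV). Each tumour had 1 array, and 17709 transcript clusters (probe groups that report 1 gene) carried a gene symbol. Array medians lay between 6.96 and 7.07 on the log2 scale, and between 36.3% and 44.3% of the clusters exceeded the 95th percentile of the negative control probes of their array. Values spread wider in BORA arrays: their lower quartiles were 4.65 to 4.76 and their upper quartiles 9.45 to 9.55, against 4.85 to 4.88 and 9.37 to 9.43 in EV arrays. Of the genes below the negative control percentile in both groups 67.4% were lower in BORA tumours, and of the other genes 34.7%. After quantile normalization these shares were 54.4% and 48.5%. In the deposited values, positive controls exceeded negative controls in a share of 0.9721 to 0.9763 of pairs in BORA arrays. In EV arrays that share was 0.9643 to 0.9715, so this measure of array quality differed between the groups without overlap. The number of arrays limits the precision. The labels do not say whether the tumours of a group came from separate animals or from more than 1 transfected cell pool. The p-values of single genes therefore measure only the spread between these samples, which may be technical. Camera p-values at the preset correlation compare list members with other genes and treat genes as nearly independent. They therefore mainly reflect spread between genes, not between tumours. Over 8 arrays the mitotic list had a mean of 0.42 with an SE of 0.48 between tumours. Its camera adjusted p was 0.00205, and 0.767 with an estimated correlation.

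The tumour EV replicate 1 stood apart from the other 7. It held very high levels of squamous epithelial genes, among them S100A8 (15.03 against 4.52 ± 1.26 in EV replicates 2 to 4, SD, n = 3), KRT1 (14.15 against 4.43), DSG3 (15.01 against 5.48) and SPRR1A (15.38 against 5.09). It held far less of MFAP5 (5.91 against 13.07 ± 0.81), NRP1 (5.72 against 10.75 ± 0.90) and PTPRC (6.91 against 12.46 ± 0.42), the gene of the CD45 phosphatase. PAX8 and EPCAM, genes of ovarian carcinoma and of epithelium, were at 12.02 and 13.52 there and at 13.23 ± 0.39 and 14.06 ± 0.62 in EV replicates 2 to 4. These genes were chosen after their values were seen. In this array 132 clusters lay more than 3 log2 units above every other array and 15 lay more than 3 below, against at most 1 in any other array. Its correlation with the others over all clusters was 0.943 to 0.954, while the other 7 arrays correlated with each other at 0.981 to 0.992. Because this array stood apart, each comparison is given over all 8 arrays, as planned, and again over the 7 arrays without EV replicate 1, a choice made after the data were seen. Leaving out any 1 of the other 7 arrays also moved the count of risen clusters by more than 1.5 times, in each case down, as given below.

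**Figure D1:**
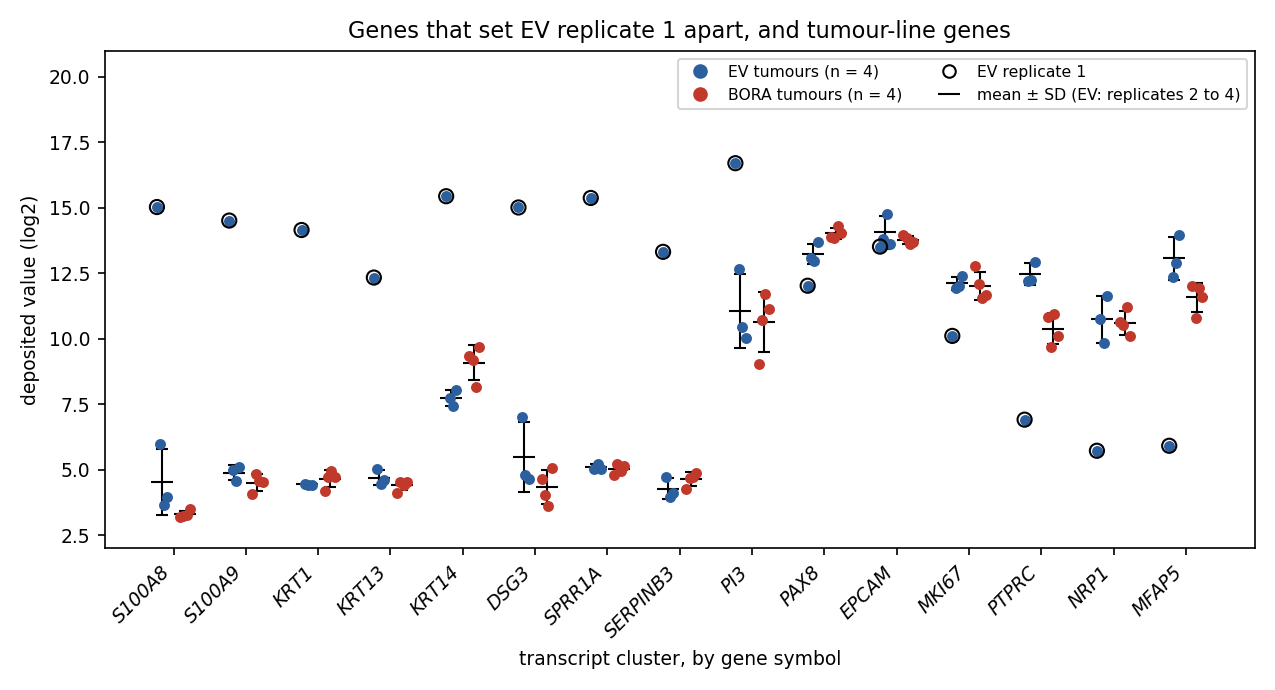
Deposited log2 values of squamous epithelial genes, of genes of the tumour line and of genes that were low in EV replicate 1, with EV tumours in blue, BORA tumours in red and EV replicate 1 circled. Horizontal marks are means with SD bars, over the 4 BORA tumours and over EV replicates 2 to 4; S100A8 was at 15.03 in EV replicate 1 and at 4.52 on average in the other EV tumours.

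The first comparison asks whether the BORA tumours carried more BORA transcript, which checks the labels. BORA (transcript cluster TC1300007483.hg.1) was at 12.76 ± 0.23 (SD, n = 4) in BORA tumours and at 6.63 ± 0.57 (SD, n = 4) in EV tumours, a rise of 70.1-fold (log2 difference 6.13, SE 0.27). The lowest BORA tumour was at 12.55 and the highest EV tumour at 7.32, and the EV mean lay below the 95th percentile of the negative controls, so the fold rests on an EV level near background. The limma adjusted p was 2.38e-05, and a two-sided exact permutation test over 70 splits gave p = 0.0286, the smallest it allows. Without EV replicate 1 the log2 difference was 5.98 (SE 0.26).

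The second comparison asks which other genes differed between BORA and EV tumours. MMP14, a membrane-anchored collagenase that cleaves the pericellular matrix, rose by 13.7-fold, from 6.44 ± 0.88 to 10.21 ± 0.18 (SD, n = 4 each; log2 difference 3.78, SE 0.38, limma adjusted p = 0.0197). IFI6, an interferon-induced gene, rose by 7.88-fold, from 8.63 ± 0.072 to 11.61 ± 0.74 (SE of the log2 difference 0.32, adjusted p = 0.0227). HSPG2, which encodes the basement membrane proteoglycan perlecan, rose by 5.23-fold (SE 0.29), and ERG, an ETS transcription factor typical of endothelial cells, by 5.29-fold (SE 0.32). In EV tumours MMP14 and ERG lay below the 95th percentile of the negative controls on average, so their folds, like that of BORA, rest on a level near background.

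Other rises among the 12 largest were those of KCNAB1 (a potassium channel subunit, 6.14-fold), TM4SF4 (a membrane protein with 4 membrane-spanning segments, 6.08-fold), CSMD1 (4.48-fold), CENPT (a kinetochore protein, 3.32-fold), RNF128 (a ubiquitin ligase, 3.17-fold), ABCC4 (an efflux transporter, 3.11-fold) and BCAR1 (the adhesion scaffold p130Cas, 3.07-fold), with adjusted p between 0.0350 and 0.0386. TM4SF4 lay below the negative control percentile in EV tumours, and the means of KCNAB1, CSMD1, CENPT and RNF128 lay below it in both groups (at most 7.22, where the percentile of the BORA arrays averaged 7.82), so the sizes of these folds are uncertain. CADM1, TTYH3, IRF9, FGF5 and BMPR1B, outside the rule for named genes and chosen after their values were seen, rose by log2 differences of 1.53, 1.13, 1.11, 1.11 and 1.07, FGF5 from levels below the percentile in both groups. In all, 18 clusters, the BORA transcript among them, rose and 0 fell in limma at an adjusted p under 0.05, while at an unadjusted p under 0.05 1305 were higher and 1269 lower. The lower clusters with the smallest p did not pass: LY6G6E was at a log2 difference of -1.34 (adjusted p = 0.0625), LIPG, a lipase gene, at -1.07 (0.0759), MBD3L3 at -0.80, GPR119 at -0.76 and AQP7 at -1.28. All but LIPG lay below the percentile in both groups. The groups did not overlap at 1658 clusters, 9.36% of all, where chance gives 2.86% on average over all splits of the arrays. The shares in single other splits were not counted, so whether this is an excess was not tested. Leaving out BORA replicates 1, 2, 3 and 4 in turn left 4, 2, 4 and 1 risen clusters, leaving out EV replicates 2, 3 and 4 left 3, 2 and 9, and the ordinary test without moderation left 1 risen and 0 fallen. The BORA transcript is part of each of these counts of risen clusters. It was the 1 cluster left without BORA replicate 4 and in the ordinary test. IFI6 passed without BORA replicate 1 or 2 or EV replicate 1 or 4, MMP14 without EV replicate 1 or 4, and of the other named rises HSPG2, ERG, TM4SF4, RNF128 and BCAR1 passed only without EV replicate 1.

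**Figure D2:**
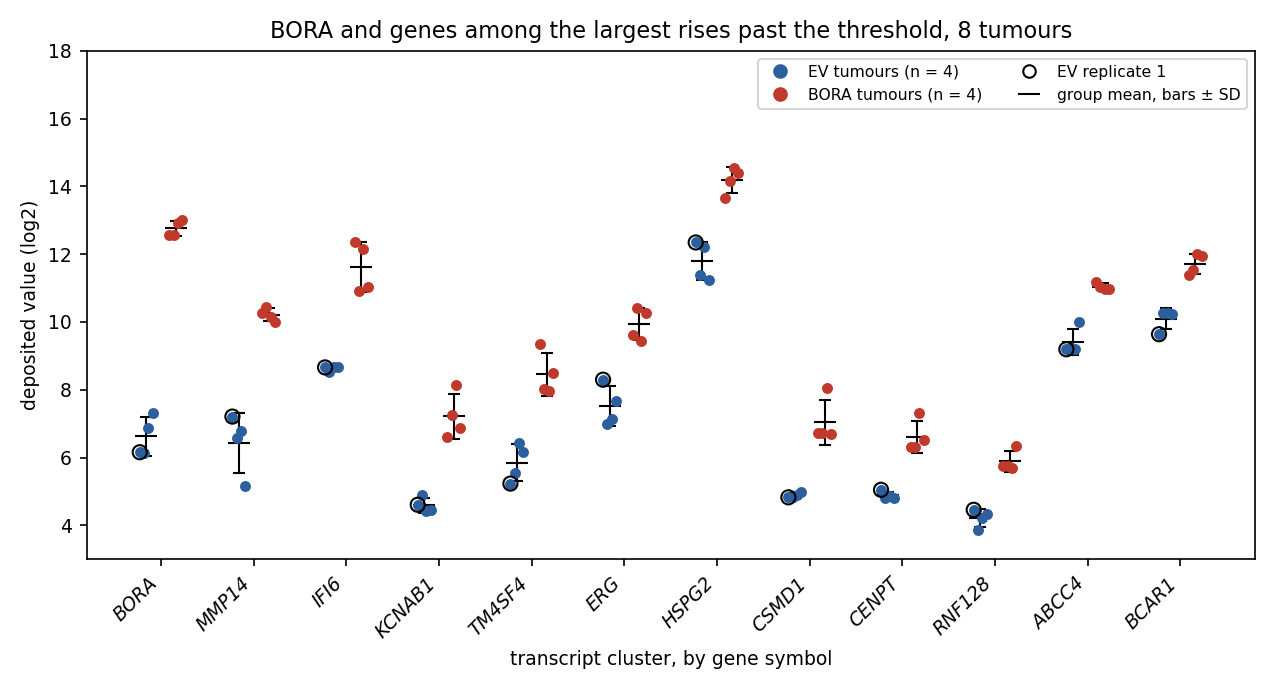
Deposited log2 values of BORA and of genes among the 12 largest rises past the threshold over 8 arrays, with EV tumours in blue, BORA tumours in red and EV replicate 1 circled; horizontal marks are group means with SD bars (n = 4 each). Every BORA tumour lies above every EV tumour for each gene, as for MMP14 with 9.99 as the lowest BORA value and 7.21 as the highest EV value.

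Over the 7 arrays left without EV replicate 1, the largest named rise after BORA was that of MMP13. MMP13 and MMP1, collagenases of the interstitial matrix, rose by 45.2-fold (log2 difference 5.50, SE 0.68, limma adjusted p = 0.00998) and 10.2-fold (3.35, SE 0.49, adjusted p = 0.0173). The EV values of MMP13 were 10.27, 8.56 and 6.36, the last below the negative control percentile of its array. MMP13 was at 12.04 in EV replicate 1, above the other EV tumours, and at 13.21 in the lowest BORA tumour. The log2 difference was 6.44 without EV replicate 2 and 4.48 without EV replicate 4, so the size of its fold is uncertain. That of MMP1 was 2.59 without EV replicate 3. MMP14 rose by 16.4-fold (adjusted p = 0.000739). CEMIP, which takes part in hyaluronan degradation, rose by 6.34-fold and ENPP2, which encodes the lysophospholipase autotaxin, by 9.73-fold. Over 8 arrays the folds of MMP13 and MMP1 were 24.0 and 16.0 and did not pass (adjusted p = 0.137 and 0.0994). ST8SIA4, a polysialyltransferase, fell by 2.39 on the log2 scale (SE 0.21, adjusted p = 0.000982), and PTPRC fell by 2.07 (SE 0.31, adjusted p = 0.0194). Over 8 arrays their log2 differences were -1.39 and -0.68 and did not pass (limma adjusted p = 0.462 and 0.803). In EV replicate 1, the array left out, they were at 6.78 and 6.91, below every BORA tumour, so both falls depend on leaving it out.

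The remaining named rises without EV replicate 1 were PALMD (9.30-fold), FLI1, an ETS factor of endothelial and blood cells (6.27-fold), F2RL2, a thrombin receptor gene (5.44-fold), and IFI6, ERG, KCNAB1 and HSPG2, which also rose over 8 arrays. The log2 differences of FLI1 and F2RL2 fell from 2.65 and 2.44 to 1.90 and 1.85 without EV replicate 3. Those of ENPP2 and PALMD went from 3.28 to 2.64 without BORA replicate 1 and from 3.22 to 4.19 without EV replicate 2. PALMD was at 14.97 in EV replicate 1, above every BORA tumour. The remaining named falls were those of USP17L22 (a member of a multigene family whose probes may not separate its copies, 2.89-fold), AQP7 (a glycerol channel gene, 2.69-fold), LY6G6E (2.64-fold), MLLT11 (2.42-fold), PLA2G5 (a secreted phospholipase gene, 2.32-fold), SLC10A6 (2.24-fold), LIPG (2.18-fold), LY6G6C (2.17-fold), FBXL13 (2.17-fold) and FRMD3 (2.08-fold). LY6G6C and SLC10A6 were at 10.12 and 7.87 in EV replicate 1, above the other 7 arrays. AQP7, LY6G6E, MLLT11, PLA2G5 and LIPG lay above every BORA tumour there. FRMD3 (5.42) lay below every BORA tumour in that array, and FBXL13 (6.62) and USP17L22 (4.69) lay inside the BORA range, against the direction of their falls. Means below the negative control percentile were those of MMP14, ENPP2, PALMD, ERG, FLI1 and F2RL2 in EV tumours, of PLA2G5 and FBXL13 in BORA tumours, and of CEMIP, KCNAB1, USP17L22, AQP7, LY6G6E, SLC10A6, LY6G6C and FRMD3 in both. The sizes of their folds are therefore uncertain. In all, 77 clusters rose and 14 fell, and the 77 included all 18 that rose over 8 arrays. MMP14, MMP13, CEMIP, IFI6, ERG, KCNAB1, HSPG2 and ST8SIA4 passed whichever further array was left out, while the other named genes lost the call in part. Of these, MMP1, PTPRC and LY6G6E passed in 5 of 7 cases, PLA2G5 in 4, ENPP2, FLI1, AQP7 and LY6G6C in 3, and PALMD, F2RL2, USP17L22, MLLT11, SLC10A6, LIPG, FBXL13 and FRMD3 in 1. Leaving out BORA replicates 2, 3 or 4 or EV replicate 3 gave 24, 32, 36 and 46 rises, and leaving out BORA replicates 1 to 4 or EV replicates 2 or 4 gave 9, 1, 2, 4, 9 and 46 falls. The ordinary test left 0 of either, where limma had 1363 higher and 1350 lower at an unadjusted p under 0.05.

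Interferon-stimulated genes were higher together in BORA tumours. Their mean log2 difference over 19 measured members was 0.84 (SE 0.084; camera adjusted p = 1.59e-10; adjusted p = 0.132 with an estimated correlation). IFI6 and IRF9, a subunit of the interferon-activated factor ISGF3, rose, while 17 members did not pass, among them MX1 (1.58) and IFI44L (1.95); adjusted over the list alone, 9 rose. All 4 BORA tumours had a higher list score than all 4 EV tumours. With the fry test this was the only list called, over 8 arrays (fry adjusted p = 0.00674) and over 7 (0.0236). Of the 19 members, 5 exceeded the negative control percentile in both groups and 13, IFI44L and OAS2 among them, in neither. Without EV replicate 1, 7 members rose, including the RNA sensors OAS1 (1.54) and OAS2 (1.95) and the antiviral GTPase MX1 (1.56), 12 did not pass, and 11 rose adjusted over the list alone. The mean log2 difference was then 0.85 (camera adjusted p = 6.59e-12; adjusted p = 0.332 with an estimated correlation), and ISG15 (-0.023) and IFIT2 (-0.011) were among the 3 members with a value below 0.

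NF-kB and inflammatory cytokine genes had the largest mean log2 difference of the fixed lists with higher values, 1.46 over 16 members (SE 0.60; camera adjusted p = 1.02e-07; adjusted p = 0.458 with an estimated correlation). All 16 members had values above 0, among them the neutrophil chemokine genes CXCL8 (3.21), CXCL2 (1.47) and CXCL3 (1.41) and the monocyte chemokine gene CCL2 (1.58). None passed over all genes in limma (0 of 16), and 7 rose adjusted over the list alone. BORA replicate 1 had a list score of -0.90, within the EV range of -1.39 to -0.32, and without it CXCL8 was at 4.10. Without EV replicate 1 the mean was 1.33 (camera adjusted p = 6.75e-08; adjusted p = 0.423 with an estimated correlation), again with 0 of 16 past the threshold and 9 adjusted over the list alone.

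Extracellular matrix and mesenchymal genes were also higher as lists. The collagens and extracellular matrix list had a mean log2 difference of 0.89 over 21 members (SE 0.27; camera adjusted p = 0.000112; adjusted p = 0.458 with an estimated correlation). Its members COL4A1 (2.37), COL5A2 (1.66), COL12A1 (1.10) and POSTN (0.80) did not pass; over all genes 0 of 21 did, and adjusted over the list alone 5 rose. The mesenchymal list had a mean of 0.53 over 18 members (camera adjusted p = 0.00195; adjusted p = 0.290 with an estimated correlation), 0 of them past the threshold, with 2, CDH2 (1.71) and TGFBI (1.93), rising adjusted over the list alone. Over the 7 arrays the means were 0.75 (adjusted p = 0.000243; adjusted p = 0.423 with an estimated correlation) and 0.55 (adjusted p = 0.00162; adjusted p = 0.423 with an estimated correlation). CDH2, the N-cadherin gene, then rose (1.88, limma adjusted p = 0.0194), 17 mesenchymal members and all 21 matrix members did not pass, and 2 and 6 rose adjusted over the list alone. Without dim clusters below the median the mesenchymal call ended over 8 arrays (adjusted p = 0.295) and over 7 (0.137), although its means stayed at 0.52 and 0.58. The epithelial junction and keratin list was at -0.28 (camera adjusted p = 0.395) with MUC1 at 1.59 and CLDN4 at -0.94, and 0 of 18 passed. Without EV replicate 4 it was lower over 8 arrays (-0.58, adjusted p = 0.0240) and over 7 (-0.60, adjusted p = 8.41e-05), and over 7 also without dim clusters below the median (-0.20, adjusted p = 0.0366). Over 7 arrays its mean was -0.20 (adjusted p = 0.235) and turned to 0.13 without EV replicate 3 (adjusted p = 0.659).

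Genes of the cell cycle, the process in which BORA acts, depended on EV replicate 1. Over 8 arrays the mitotic entry and mitosis list was higher (mean 0.42 over 30 members, SE 0.48; camera adjusted p = 0.00205; adjusted p = 0.767 with an estimated correlation), with CDC20 at 1.04, CDC25B at 0.94 and UBE2C at 0.75 and 0 of 30 past the threshold. The list score of EV replicate 1 was -1.75, against -0.18 to 0.18 in the other EV tumours and -0.35 to 0.45 in BORA tumours. Without that array the mean was -0.019 (SE 0.22, adjusted p = 0.917), and without BORA replicate 1 as well it was lower (-0.17, adjusted p = 0.0499). The 8-array call also ended without BORA replicate 1 alone (0.27, adjusted p = 0.0635), with array weights (0.15, adjusted p = 0.182) and without dim clusters below the median (0.41, adjusted p = 0.266). The G1/S and DNA replication list went from 0.25 (adjusted p = 0.0649; E2F1 at 0.94) to -0.071 without EV replicate 1 (adjusted p = 0.639), with 0 of 25 past the threshold in either. It was higher over 8 arrays without BORA replicates 3 or 4 or EV replicates 2, 3 or 4 (0.32 to 0.38, adjusted p = 0.00683 to 0.0314) and after centring on the median (0.19, adjusted p = 0.0393). It was lower over 7 without BORA replicate 1 (-0.20, adjusted p = 0.0392) or without dim clusters below the median (-0.11, adjusted p = 0.0366). The G1 cyclin list was at -0.032 (adjusted p = 0.883), where adjusted over the list alone CDK6 (0.77) rose and CCND2 (-0.82) fell; over 7 arrays its mean (-0.013) and its test differed in sign.

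Among metabolic and signalling lists, oxidative phosphorylation was higher by a small mean of 0.31 (15 members, SE 0.097; camera adjusted p = 0.00142; adjusted p = 0.458 with an estimated correlation), with SDHA at 0.75 and NDUFV1 at 0.79, 0 past the threshold and 2 adjusted over the list alone. Without EV replicate 1 it was at 0.26 (adjusted p = 0.00484; adjusted p = 0.423 with an estimated correlation). The call ended without dim clusters below the median over 8 arrays (adjusted p = 0.0624) and over 7 (0.0751), with the means unchanged, and over 7 after quantile normalization (0.16, adjusted p = 0.105). The MAPK feedback list (0.43, adjusted p = 0.0148; SPRY4 at a fold of 2.84 and PHLDA1 at a log2 difference of 0.70) and the cholesterol and fatty acid synthesis list (0.28, adjusted p = 0.0233; SREBF1 at 1.06 and FASN at 0.70) were called over 8 arrays, with adjusted p = 0.458 with an estimated correlation for each, 0 members past the threshold, and 0 and 1 adjusted over the list alone. Neither call held without EV replicate 1, where the means were 0.28 and 0.18 (adjusted p = 0.0656 and 0.134). Both also ended after quantile normalization (0.33 and 0.17, adjusted p = 0.118 and 0.190) and with array weights (0.31 and 0.18, adjusted p = 0.0645 and 0.115). With either filter on dim clusters the calls ended too, with means of 0.43 for the MAPK list and 0.28 for the cholesterol list. The cholesterol call also ended without BORA replicate 1 (0.22, adjusted p = 0.0657) and the MAPK call without BORA replicate 3 (0.30, adjusted p = 0.0706). Over 7 arrays the MAPK list was higher without BORA replicate 1, 2 or 4 (0.32, 0.34 and 0.33; adjusted p = 0.0352, 0.0269 and 0.0428) and after centring (0.23, adjusted p = 0.0431).

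In all 8 lists of markers of other cell types most members had lower values in BORA tumours (73 lower and 22 higher over 8 arrays), and without EV replicate 1 this held for 7 lists (70 and 25), all but that of skin keratinocytes. Dim genes in general leaned the same way, as given above. After quantile normalization 66 markers were lower and 29 higher over 8 arrays, and 62 and 33 over 7. Few members exceeded the negative control percentile in both groups: 3 of 18 macrophage, 0 of 11 neutrophil and NK cell, 1 of 15 endothelial, 4 of 12 fibroblast, 1 of 14 skeletal muscle, 0 of 8 adipocyte, 2 of 10 keratinocyte and 0 of 7 erythroid markers. Neutrophil and NK cell markers were lower (-0.81 over 11 members; camera adjusted p = 0.0233; adjusted p = 0.458 with an estimated correlation), with 0 past the threshold, GZMB at -0.54 and MPO at -0.59. The call ended without BORA replicate 2 (-0.77, adjusted p = 0.0614) or 3 (-0.78, adjusted p = 0.0593), after quantile normalization (-0.72, adjusted p = 0.118) and with array weights (-0.49, adjusted p = 0.0846). EV replicate 1 had a score of 2.09 on this list, which holds S100A8 and S100A9. Without it the mean was -0.33 (adjusted p = 0.0381; adjusted p = 0.423 with an estimated correlation). That call ended without BORA replicate 2 (-0.29, adjusted p = 0.0769), BORA replicate 3 (-0.31, adjusted p = 0.0813) or EV replicate 4 (-0.27, adjusted p = 0.142), after quantile normalization (-0.24, adjusted p = 0.173) and with array weights (-0.33, adjusted p = 0.0644). Skeletal muscle markers were at -0.31 (adjusted p = 0.00871; adjusted p = 0.458 with an estimated correlation; DES at -0.84), and at -0.18 (adjusted p = 0.134) without EV replicate 1. The 8-array call ended after quantile normalization (-0.21, adjusted p = 0.118) and with array weights (-0.22, adjusted p = 0.0810). Macrophage and myeloid markers were at -0.18 (adjusted p = 0.0758; without EV replicate 3 -0.20, adjusted p = 0.0411; with array weights -0.39, adjusted p = 0.00492) and, without EV replicate 1, at -0.37 (18 members, adjusted p = 0.00559; adjusted p = 0.423 with an estimated correlation). There PTPRC fell, 17 members did not pass, among them CD163 (-1.26) and C1QA (-0.75), and 2 fell adjusted over the list alone. This call ended without EV replicate 2 (-0.20, adjusted p = 0.180) and without dim clusters below the median (-0.32, adjusted p = 0.0751), and over 8 arrays the means in these 2 settings were 0.00079 and 0.085.

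Endothelial markers split: ERG rose, CDH5 (VE-cadherin, 2.28) and PECAM1 (CD31, 1.56) rose adjusted over the list alone but not over all genes, and 10 of 15 members, among them CLDN5 (-0.49), had values below 0. The list's mean was 0.27, its median -0.20 and its camera adjusted p 0.958. Fibroblast and pericyte markers had a mean of 0.014, a median of -0.19 and a test pointing down (adjusted p = 0.662), with POSTN (0.80) rising adjusted over the list alone and 0 of 12 over all genes. Adipocyte (-0.50, adjusted p = 0.0649), skin keratinocyte (-1.06, adjusted p = 0.0676) and erythroid markers (-0.075, adjusted p = 0.662) were not called. The keratinocyte list was lower without EV replicates 2, 3 or 4 (-1.49, -1.46 and -1.42; adjusted p = 0.00953, 0.0193 and 0.0326) and with the replicate number as a block (adjusted p = 0.0363), and at 0.14 without EV replicate 1 (adjusted p = 0.700). The adipocyte list was lower without BORA replicate 4, over 8 arrays (-0.55, adjusted p = 0.0314) and over 7 (-0.30, adjusted p = 0.0428). Over 7 arrays the medians of the endothelial (-0.16) and fibroblast lists (-0.17) again differed in sign from their means (0.23 and 0.050).

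The other lists were not called over 8 or 7 arrays. The list members described in this part and above that lay below the negative control percentile in both groups included CCL2, CDH2, POSTN, E2F1, CCND2, AXIN2, BMP4, BAD and ALDH1A1. IFI44L, OAS2, CDH5 and most members of the cell type marker lists also did. Wnt target genes had a mean of 0.46 (camera adjusted p = 0.201), with DKK1 (2.63), AXIN2 (0.99) and BMP4 (1.49) rising adjusted over the list alone; DKK1, a secreted Wnt inhibitor, rose over all genes without EV replicate 1 (1.99, limma adjusted p = 0.0323). Genes of the BCL2 family were at 0.15 (adjusted p = 0.225), with the pro-apoptotic genes PMAIP1 (1.17) and BAD (0.71) rising adjusted over the list alone. The p53 targets had a mean of 0.023 and a median of -0.14 (adjusted p = 0.882), with CCNG1 (0.78) rising adjusted over the list alone. Homologous recombination and Fanconi repair genes were at 0.15 (adjusted p = 0.395; over 7 arrays without BORA replicate 1 -0.25, adjusted p = 0.0462). The unfolded protein response was at 0.099 (adjusted p = 0.346) and ribosomal proteins at 0.13 (adjusted p = 0.201; without EV replicate 3 0.20, adjusted p = 0.0411). The ovarian tumour and stem cell genes were at 0.066 (adjusted p = 0.395), with ALDH1A1 (0.84) and PAX8 (1.10) rising adjusted over the list alone. The receptor tyrosine kinase and PI3K list had a mean of 0.061 and a median of -0.051 (adjusted p = 0.662; GRB7 at 1.06), and over 7 arrays a mean of 0.024 and a median of -0.0085. Hypoxia and glycolysis genes were at -0.041 (adjusted p = 0.883; ANGPTL4 at a fold of 2.38, VEGFA at a log2 difference of -0.80). Without BORA replicate 1 they were higher over 8 arrays (0.41, adjusted p = 0.00185) and over 7 (0.56, adjusted p = 2.23e-06), ANGPTL4 was at 2.04 and VEGFA at -0.066 over 8 arrays, and VEGFA at 0.096 over 7. Means near 0 turned sign under some settings. Over 8 arrays the p53 targets ranged from -0.090 to 0.18, the repair genes from -0.17 to 0.32, the hypoxia genes from -0.24 to 0.41, the G1 cyclin list from -0.090 to 0.11, the receptor tyrosine kinase list from -0.0012 to 0.11 and the fibroblast markers from -0.17 to 0.12. Over 7 arrays the mitotic, G1/S, G1 cyclin, hypoxia, unfolded protein, receptor tyrosine kinase, ovarian, fibroblast and ribosomal lists also turned.

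**Figure D3:**
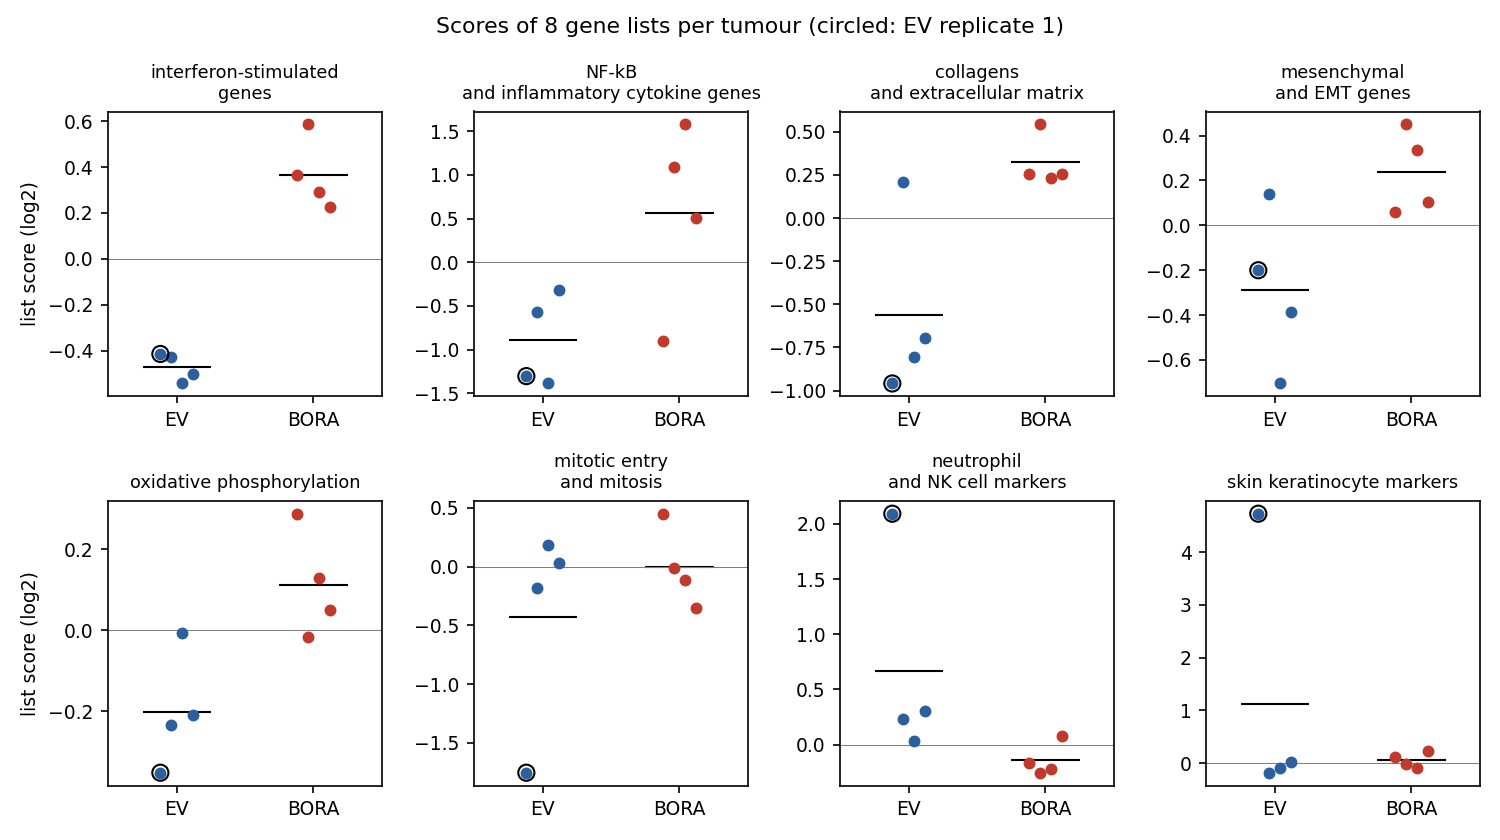
Scores of 8 gene lists per tumour, each the mean over the list's members of the log2 value minus the gene's mean over the 7 arrays without EV replicate 1; lines are group means (n = 4 each) and EV replicate 1 is circled. Interferon-stimulated genes separate the groups in every tumour, while the mitotic, neutrophil and keratinocyte scores set EV replicate 1 apart at -1.75, 2.09 and 4.73.

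In EV replicate 1, neighbouring genes also shifted together. Over 7057 expressed genes placed in genome order, medians of 41 neighbouring genes in EV replicate 1, minus the mean of the other EV tumours, reached -1.07 between UCP2 and TRPC6, -1.05 between TAGLN and NFRKB, -0.99 between DCDC2 and H3C11 and -0.98 between FBXL5 and SHISA3. The highest median was 0.65. In the other 7 arrays the largest size was 0.21 to 0.52.

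**Figure D4:**
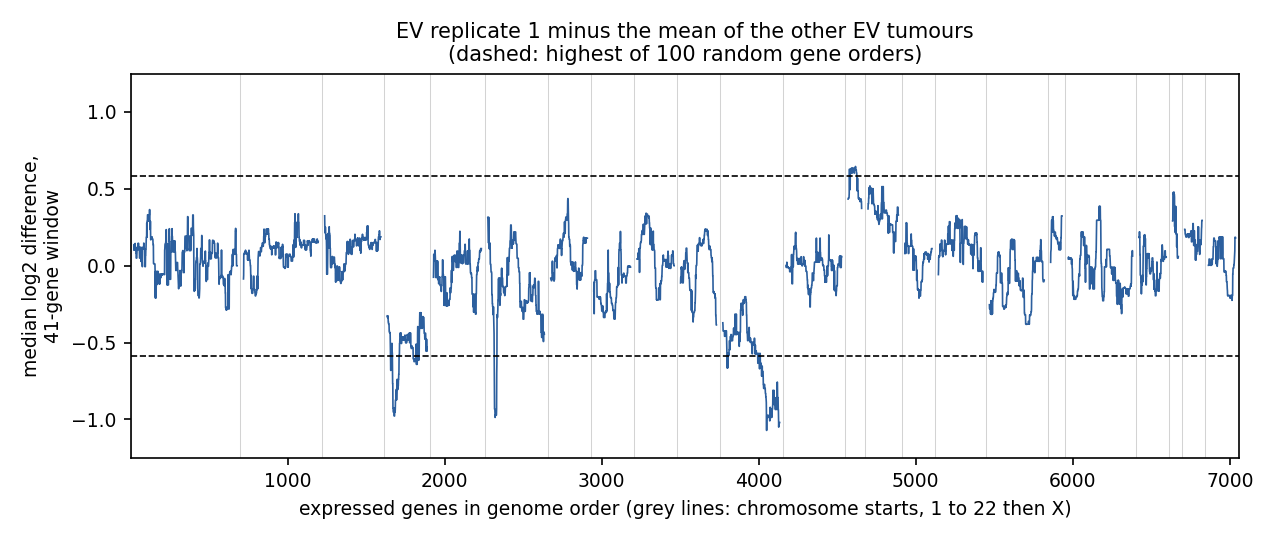
Medians over 41 neighbouring expressed genes of the log2 difference between EV replicate 1 and the mean of EV replicates 2 to 4, along 7057 genes in genome order, with grey lines at chromosome starts and dashed lines at the highest of 100 random gene orders (0.585). The lowest medians were -1.07 between UCP2 and TRPC6 and -1.05 between TAGLN and NFRKB. Adjacent windows share genes, so runs of low medians arise in part from the windows themselves.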

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

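The tests of EV replicate 1 in this part were chosen after its values were seen; the counts over other splits of the arrays were planned before they were run. A value was marked when it lay far from its own group of 4 by Dixon's test at the 95% level, which chance does in about 1 of 20 groups; 17 of 100 tests did so, 9 of them in EV replicate 1.

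EV replicate 1 was marked for its scores of skin keratinocyte markers (4.73), neutrophil and NK cell markers (2.09), adipocyte markers (1.15), skeletal muscle markers (0.617), G1/S and DNA replication genes (-1.23) and MAPK feedback genes (-0.75), for its level of BCAR1 (9.64), for its median correlation with the other arrays (0.948) and for its place on the first principal component (103.5, where the others lay between -25.1 and -4.07). Most of the adipocyte score came from FABP4, at 12.41 in this array and at 3.95 on average in EV replicates 2 to 4. Mouse skin in the tumour piece is argued against as the whole source of the risen genes by PI3, CLEC2B and S100A12, which mice lack and whose median excess over the highest other array was 4.05. Of these, S100A12 (7.48) lay below the negative control percentile of EV replicate 1 (8.24), while PI3 (16.70) and CLEC2B (10.87) exceeded it. A lower share of SK-OV-3 RNA alone is argued against by 15 clusters that fell further than PAX8 allows. They lay more than 2.99 log2 units below every other array, against at most 1 such cluster in another array. A fault of hybridisation is argued against by the spiked-in controls, 8 of 8 of which lay inside the range of the other arrays. Such controls do not test the sample's own RNA. EV replicate 1 had the lowest share of clusters above the negative control percentile (36.3%) and the highest such percentile (8.24) of all arrays. A genetically different cell population may account for the difference of this array, as a hypothesis: neighbouring genes shifted together by up to 1.07 in size, against 0.585 in the highest of 100 random orders. However, EV replicates 2 to 4 (0.51 to 0.52, random orders 0.25 to 0.36) and BORA replicates 2 and 3 (0.30 and 0.31, random orders 0.26 and 0.27) also exceeded theirs, of which each had 20. Random orders also part neighbours that are regulated together, so exceeding them does not by itself show a genetic difference. Whether a different population would be a subclone of the line, human cells of another origin or a wrong label stays open. So does whether RNA quality or a squamous programme of the same cells adds to the difference. PAX8, EPCAM and GRB7 (11.14 there, 12.11 ± 0.21 in the other EV tumours) were present, and CDKN2A was near 4 or below in all 8 arrays. KRT7, a keratin gene of the epithelial list, was lower there (10.01, against 13.91 ± 1.60 in the other EV tumours).

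Among the other marked values, IFI6 was lowest in EV replicate 2 (8.53), although the EV tumours spread over only 0.072 (SD), and ABCC4 was highest in EV replicate 4 (9.99). In BORA tumours, CSMD1 was highest in replicate 3 (8.04) and RNF128 in replicate 4 (6.36). The score of collagens and extracellular matrix was highest in BORA replicate 2 (0.543), that of MAPK feedback genes in BORA replicate 3 (0.531) and that of skeletal muscle markers in BORA replicate 4 (0.0252). Hypoxia and glycolysis genes were lowest in BORA replicate 1 (-1.32). In data outside the comparisons, 2 transcript clusters with no gene listed passed the threshold when all rows were tested over 8 arrays.

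Over the 8 arrays, 1 of the 35 splits into groups of 4, the real one, gave as many called clusters (18, where the highest other split gave 0). Over the 7 arrays it was again 1 of 35 (91, where the highest other split gave 4). A rank of first among 35 splits is the strongest result these arrays allow. Over 8 arrays the BORA transcript, which the vector sets, would alone give that rank, since the highest other split gave 0. The 8-array rank therefore cannot decide whether the other rises arose by chance. Over 7 arrays the count argues against chance but cannot exclude it. For called lists the splits do not argue against chance. Over 8 arrays 14 of 35 splits gave as many as the real 10 (highest other 15), and over 7 arrays 14 of 35 as many as the real 7 (highest other 11). The list test took a correlation of 0.01 between genes, while the estimated values reached 0.883, and 0 lists passed with the estimates; whether this or structure among the tumours gave calls in other splits was not tested.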

How the results depend on the processing

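The fits without EV replicate 1 and their alternatives were chosen after the data were seen. The rise of BORA kept its direction under every alternative and its call under all but the ordinary test over 7 arrays (5.98, adjusted p = 0.137); adjusted p ran from 1.62e-06 to 0.0191 over 8 arrays and from 4.18e-08 to 0.137 over 7. The replicate numbers of the labels did not pair the tumours (correlations of same-numbered tumours -0.11 to 0.071), and the replicate block left 1 cluster higher, the BORA transcript. Of the 18 higher clusters over 8 arrays, array weights gave 43, the median filter on dim clusters 9, the ordinary test 1 (the BORA transcript), unadjusted p with a 1.5-fold minimum 801, and leaving out 1 array 1 to 77. For the 0 lower clusters these were 5 with array weights, 1 with the trend and robust fit, 1 with all rows, 479 unadjusted and 0 to 14 leaving out 1 array. The 8 higher lists became 5 with array weights, 3 with the median filter, 0 with an estimated correlation, 1 with fry and 5 to 10 leaving out 1 array; the 2 lower lists became 0, 1, 0, 0 and 0 with quantile normalization, array weights, the median filter, an estimated correlation and fry, and 1 to 4 leaving out 1 array. Over 7 arrays the 77 higher clusters became 46 after centring, 51 with the median filter, 0 with the ordinary test, 40 with all rows, 783 unadjusted and 24 to 106 leaving out 1 array. The 14 lower became 28 with the trend and robust fit, 24 with array weights, 8 with the median filter, 0 with the ordinary test, 5 with all rows, 555 unadjusted and 1 to 46 leaving out 1 array. The 5 higher lists became 3, 0 and 1 with the median filter, an estimated correlation and fry; the 2 lower became 1 with quantile normalization, 1 with array weights, 0 with an estimated correlation, 0 with fry and 1 to 5 leaving out 1 array. The hypoxia list turned from -0.041 to 0.413 without BORA replicate 1 and the mitotic list to -0.019 without EV replicate 1; leaving out 1 array, they ranged from -0.24 to 0.413 and from -0.019 to 0.63. Over 8 arrays, values of single called genes stayed past the threshold in 89 of their settings and lost it in 114, and values of called lists in 134 and 43; over 7 arrays these were 262 and 131, and 88 and 23. None of the called genes reversed. Fewer arrays in part cost calls by construction; other causes were not tested. Limiting clusters to those with exactly 1 symbol changed nothing, since all have 1. Signals near the negative controls, as for BORA and MMP14 in EV tumours and for KCNAB1 in both groups, limit the folds.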

Other observations

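The tests of explanations in this part were chosen after the results were seen.

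The endothelial list was not called (camera adjusted p = 0.958, 10 of 15 members lower), while single genes known from endothelium stood higher in BORA tumours. ERG rose over 8 arrays, FLI1 rose without EV replicate 1, and CALCRL, which encodes a peptide hormone receptor of endothelium, rose there too (log2 difference 1.14, limma adjusted p = 0.0427). CDH5 went from 5.44 on average in EV tumours to 7.72 in BORA tumours, and PECAM1 from 6.55 to 8.11; neither passed over all genes, over 8 arrays or 7. CDH5 and CALCRL lay below the 95th percentile of the negative controls in both groups. KDR (3.20 and 3.14), FLT1 (3.37 and 3.24) and VWF (5.98 and 5.66) were low in EV and BORA tumours alike. These genes were singled out after their values were seen, so they do not show a change of endothelial genes as a class, and no explanation was tested.

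Of 7 measured APOBEC3 cytidine deaminase genes, 3 rose without EV replicate 1: APOBEC3C by 2.38, APOBEC3G by 1.77 and APOBEC3F by 1.59 on the log2 scale (limma adjusted p = 0.0125, 0.0132 and 0.00998). APOBEC3A (-0.26), APOBEC3B (0.11), APOBEC3D (0.43) and APOBEC3H (0.030) did not pass, and no list of these genes was tested. They are near-identical in parts, so the values of single members are uncertain. In EV replicate 1 APOBEC3C (11.25) and APOBEC3F (8.75) lay above every BORA tumour. Over 8 arrays, with EV replicate 1 in, the log2 differences were 1.31, 1.31 and 0.96 and none passed. APOBEC3G lay below the 95th percentile of the negative controls in both groups, and without EV replicate 1 the EV means of the other 2 did. These genes were chosen after their values were seen.

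Interferon-stimulated genes were higher in BORA tumours under every scaling tried; the mean log2 difference was 0.836 as deposited, 0.843 after quantile normalization and 0.782 after centring on the median, which argues against the scaling of the arrays. More host immune cells cannot be told apart from a response of the tumour cells: the macrophage and myeloid markers were at -0.372 (SE 0.17) without EV replicate 1, and at -0.27 without PTPRC, but only 4 of the 18 exceeded the negative controls, 3 of them higher and 1, PTPRC, lower. An effect of BORA itself, of the vector, of the transfected cell pool or of the order of processing may each contribute, as a hypothesis. The labels do not separate them.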
